A study of Drosophila melanogaster with 32 samples.

How the data were processed

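The series measured A-to-G editing in poly(A) RNA of Drosophila S2 cells, an embryonic cell line with hemocyte-like features, that expressed an RNA-binding protein joined to the catalytic domain of the RNA deaminase ADAR. In the TRIBE method such a fusion deaminates adenosines in the transcripts it binds, and the resulting inosine is read as guanosine after sequencing. HyperTRIBE uses a catalytic domain that carries the E488Q change. Per the labels' protocols, plasmids were transfected transiently, expression was induced with copper sulfate, and cells were sorted by fluorescence before RNA was taken for Illumina libraries.

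Of the 32 samples of the series, 7 were analysed: Hrp48 TRIBE (2 libraries), Hrp48 HyperTRIBE (2), the E488Q catalytic domain with no RNA-binding protein (2, called deaminase alone), and FMRP HyperTRIBE replicate 1. FMRP HyperTRIBE replicate 2, FMRP TRIBE, the neuronal libraries, the linker variants and the wild-type S2 library were not analysed here. Groups and replicate numbers came from the sample titles. The labels do not say whether replicates were separate cultures, so the spread between these libraries may be technical. Fisher's exact tests on gene lists do not measure this spread.

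The deposited files list edited sites with whole-number read counts per base in the RNA, and the authors give for each site the edited reads, the total reads and the percent edited. A score column in the deposited files is 10 times that percentage and was not used. Each file also holds a second set of base counts, identical between files at every site, of at least 10 reads and with 0 reads of the edited base. What was sequenced for it is not given in the sources used here. It was used only to assign the strand. The submitters' processing notes name TopHat2 2.1.1, Picard 2.8.2 and the genome build dm3, without their roles. Positions are those of dm3 in the files, as are the gene names and the EXON or INTRON mark. A site that overlaps several genes has a line for each gene. It was counted once as a site, once for each gene, and as exonic if any gene had it in an exon; shares with a neighbouring site count lines. Across the 52199 lines, the lowest values seen were 20 reads and 10% edited. The stated thresholds behind them are not given in the sources used here. The files hold only sites above these values, so a site that is not listed may have had too few reads, too little editing or no editing, and 0 was never filled in. The highest read number at a site was between 108 and 149 in every library, so read numbers were not used as expression levels.

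Of 5181 gene names, 4119 matched a current symbol of the reference table and 994 an older symbol with a single current match, leaving 68 unmatched. Names are printed as the files give them.

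Reproducible sites were those listed in both libraries of a construct at the same position and strand. Shares carry Wilson 95% intervals. These intervals cover counting error only. They take sites, genes or reads as independent, but sites cluster within genes and reads are not independent molecules. The intervals may therefore be too narrow. Numbers of sites were compared by a two-sided exact permutation test on log10 values, which with 2 libraries against 2 cannot give a p below 0.333. Editing in Hrp48 HyperTRIBE and Hrp48 TRIBE was compared at sites listed in all 4 libraries, on log2((edited + 0.5)/(unedited + 0.5)), with limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05. Sites that fail the listing minimum in any library drop out of this comparison, so a site with editing near 10% enters only when its reads in every library fell above the minimum. All sites received the same standard error of 0.581 log2 odds, because the fit found no more variation between the sites' spreads than chance gives. With 4 libraries such variation is hard to see, and the fit gave no weight to read number. The p-values may thus be too small at sites with few reads and too large at sites with many. The limma p-values therefore rest on a spread pooled over all tested sites, as if sites varied independently. A shift common to the sites of a library is not covered, so these p-values may overstate what 4 libraries can show. Differences in medians carry 95% intervals from 1000 resamplings of genes. Correlations are across sites, which are not independent replicates. Gene lists were tested by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists of each test that had a gene in its background, the genes that could pass the first criterion. These were 13 lists, and 12 in the tests on genes of at least 50 median reads, where no neuronal marker was left. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

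The limma script was tested on simulated reads at the coverage of the 298 real sites. It called 88.0% of 50 sites with a true change of 2 log2 odds, 18.0% of 50 sites with a change of 1, and 1.52% of 198 unchanged sites. The simulated sites varied independently, with no shift common to a library and no listing minimum. These rates therefore may not hold for the real sites. The list test, run on 100 random draws of list members among 3220 genes, gave a call in 2 draws. Genes drawn at random do not share coverage or number of sites, as members of a real list may. This rate therefore may not hold for the real lists.

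Named genes were chosen by a rule fixed before the data were examined. It takes Hrb27C, Fmr1 and Adar, the 10 genes with most reproducible Hrp48 HyperTRIBE sites, and the 10 genes with the tested sites of smallest adjusted p. It adds the 10 genes with most FMRP sites, the 5 with most Hrp48 sites and no FMRP site, and the 5 with most FMRP sites and no Hrp48 HyperTRIBE site. It also takes up to 5 genes with a site in both deaminase-alone libraries and up to 4 members of each fixed list. The lists cover construct and deaminase genes, cytosolic ribosomal proteins, translation factors, RNA-binding and splicing proteins, mitochondrial respiration, actin, tubulin and cell adhesion, hemocyte and extracellular matrix genes, neuronal markers, heat shock proteins and chaperones, the proteasome, cell cycle and DNA replication, metal response, and endoplasmic reticulum and secretion. Alternatives set in advance were stricter coverage (50 reads) and editing (20%) minimums, thinning of reads, percentage points, Fisher's exact test on pooled reads, a replicate block, looser overlap rules and leaving out each library. Neighbouring bases of the edited adenosines need a dm3 genome and were not analysed here.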

Results

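Editing was measured in 7 libraries of Drosophila S2 cells. They expressed Hrp48 fused to the wild-type ADAR catalytic domain (Hrp48 TRIBE, 2 libraries) or to the domain with the E488Q change (Hrp48 HyperTRIBE, 2 libraries), the changed domain by itself (deaminase alone, 2 libraries), or FMRP fused to the changed domain (FMRP HyperTRIBE, 1 library). Hrp48, the product of Hrb27C, is an hnRNP protein, and FMRP, the product of Fmr1, is a regulator of translation. Median coverage at listed sites was 27 and 29 reads in the Hrp48 TRIBE libraries, 33 and 37 in Hrp48 HyperTRIBE, 33 and 27 in the deaminase-alone libraries, and 31 in FMRP HyperTRIBE. Listed sites held 41761 and 48849 reads in all for Hrp48 TRIBE and 788102 and 979818 for Hrp48 HyperTRIBE. They held 559 and 15602 for the deaminase alone and 183333 for FMRP HyperTRIBE. Reads of a base other than adenosine or guanosine on the transcript strand, a measure of background error, were between 0.0391% (95% interval 0.0350 to 0.0437%) in Hrp48 HyperTRIBE replicate 1 and 0.179% (0.0316 to 1.01%) in deaminase-alone replicate 1.

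The first comparison asked how many transcripts and sites each construct marked, since the E488Q change was introduced to raise editing. Hrp48 HyperTRIBE listed 19706 and 22803 sites in 4036 and 4759 genes, and Hrp48 TRIBE listed 1252 and 1400 sites in 743 and 911 genes. CG11897 on 3R held 39 and 40 HyperTRIBE sites against 3 and 3 with TRIBE, and SCAP, which escorts SREBP to the Golgi, held 39 and 32 against 0 and 1. PlexA, the Plexin A receptor, held 62 and 46 against 0 and 3, and CtBP, a transcriptional co-repressor, held 54 and 45 against 3 and 1. The kinase gene hipk (34 and 38 against 0 and 3), pico (48 and 47 against 0 and 5), pcs (38 and 35 against 0 and 1) and CG31678 (32 and 33 against 0 and 2) followed. CycG, encoding cyclin G, had 35 and 33 sites with HyperTRIBE and 2 and 9 with TRIBE. Sam-S, encoding S-adenosylmethionine synthetase, had 38 and 32 against 6 and 6, and 5 of its sites were in both TRIBE libraries.

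Mean numbers of sites were 21255 ± 2190 (SD, n = 2) for Hrp48 HyperTRIBE and 1326 ± 105 (SD, n = 2) for Hrp48 TRIBE, a 16.03-fold difference that exceeded the spread between replicates (exact permutation test, p = 0.333, the smallest this design allows). The fold was 8.53 after the HyperTRIBE libraries were thinned to 0.731 and 0.575 of their reads. These were the median ratios of mean TRIBE reads to theirs at the 298 sites listed in all 4 libraries. Thinning could only remove sites, since sites just under the editing minimum are not listed, so this fold may be too low. The 298 sites had to be covered in every library, so the ratios may overstate the depth of the TRIBE libraries. For that reason the thinned fold may also be too high, and which of these weighs more was not tested. At sites with at least 50 reads the fold was 27.8. Of the HyperTRIBE sites 4489 and 6360 reached this minimum, and of the TRIBE sites 174 and 216. The HyperTRIBE libraries were deeper at the 298 sites (median 60 and 76 reads against 30 and 51), so the fold of 27.8 may be too high. The file headers place the first replicates of both Hrp48 constructs in library set 02 and the second in set 03, and within these sets the fold was 15.7 and 16.3. HyperTRIBE listed 4.88 and 4.79 sites per gene, and TRIBE 1.69 and 1.54.

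**Figure D1:**
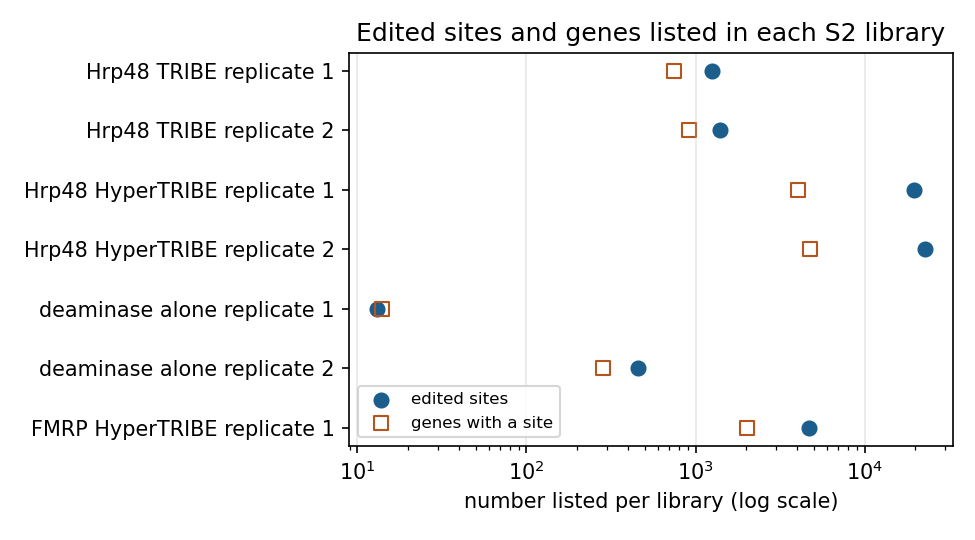
Number of edited sites (filled circles) and of genes with a site (open squares) listed in each of the 7 libraries, on a log axis. The Hrp48 HyperTRIBE libraries list 19706 and 22803 sites, and the deaminase-alone libraries 13 and 459.

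The genes of the constructs were themselves edited in Hrp48 HyperTRIBE. Hrb27C (2L, 6920834 to 6928207) held 16 and 18 sites with Hrp48 HyperTRIBE, 0 and 2 with Hrp48 TRIBE, 4 with FMRP HyperTRIBE and 0 with the deaminase alone. Fmr1 (3R, 5927434 to 5928907) held 11 and 14 Hrp48 HyperTRIBE sites and 1 FMRP site. Adar (X, 1672975 to 1677727) held 16 and 10 Hrp48 HyperTRIBE sites, 6 FMRP sites, and 1 and 0 Hrp48 TRIBE sites. Reads of a construct and of the cell's own gene cannot be separated in these files where the construct carries that gene. This holds for Hrb27C in the Hrp48 libraries, Fmr1 in the FMRP library and the catalytic domain of Adar in every library. By the design, the Hrp48 constructs carry no Fmr1 and the FMRP construct no Hrb27C.

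Editing levels were then compared at the 298 sites, in 237 genes, that all 4 Hrp48 libraries listed. Editing rose at 83 sites in 76 genes with HyperTRIBE and fell at none (limma, adjusted p under 0.05), and at an unadjusted p under 0.05 no site was lower. The exonic site of Ald, encoding aldolase (3R, 22080705), rose from 20.1% ± 13.4 (SD, n = 2) to 75.01% ± 0.57, a change of 3.63 ± 0.58 log2 odds (SE, limma adjusted p = 2.41e-07). The site of Kr-h2 (2L, 6073618) rose from 18.1% ± 8.72 to 63.3% ± 1.17 (SD, n = 2; limma adjusted p = 7.66e-05). Ef1alpha48D, encoding translation elongation factor 1 alpha (2R, 7782933), rose from 19.5% ± 4.62 to 62.9% ± 1.15 on 101 to 124 reads per library. In scf (3L, 1299832) editing rose from 26.02% ± 7.28 to 70.2% ± 1.56, and in Pgi, encoding phosphoglucose isomerase (2R, 4798624), from 30.0% ± 18.9 to 71.6% ± 2.05. The next were CG10077 (3L, 6943243) at 21.3% against 62.5%, CG18812 (2R, 3606409) at 15.4% against 52.1%, RpL4 (3R, 23750548) at 17.1% against 54.3%, CG14767 (2R, 4605817) at 13.6% against 46.9%, and Sec63 (3L, 7356694) at 14.4% against 50.01%. All 10 lie in exons. The lowest estimate was at Lam, encoding a nuclear lamin (2L, 5545857), with 48.8% in TRIBE and 30.5% in HyperTRIBE (limma adjusted p = 0.146).

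The mean was higher in HyperTRIBE at 252 of the 298 sites (84.6%), by a median of 0.86 log2 odds (1.20 without TRIBE replicate 1 and 0.54 without TRIBE replicate 2), and both HyperTRIBE libraries lay above both TRIBE libraries at 181 sites (60.7%, where chance gives 16.7%). Median editing was 26.04% and 16.6% in the TRIBE libraries at 30 and 51 reads, and 34.8% and 35.2% in the HyperTRIBE libraries at 60 and 76 reads. Within library set 02 editing was higher with HyperTRIBE at 205 of the sites, by a median of 7.62 percentage points over all 298, and within set 03 at 265, by 16.6 points. Without HyperTRIBE replicate 1 or replicate 2, only 1 site passed the threshold, and without TRIBE replicate 1, 171 sites were higher and 1 lower, and without TRIBE replicate 2, 81 were higher and 9 lower. The count was 31 of 56 sites with at least 50 reads in every library, 215 of 1395 (and 1 lower) where 1 TRIBE library sufficed, and 127 (and 1 lower) with Fisher's exact test on pooled reads, which counts reads as independent and leaves out the spread between libraries.

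**Figure D2:**
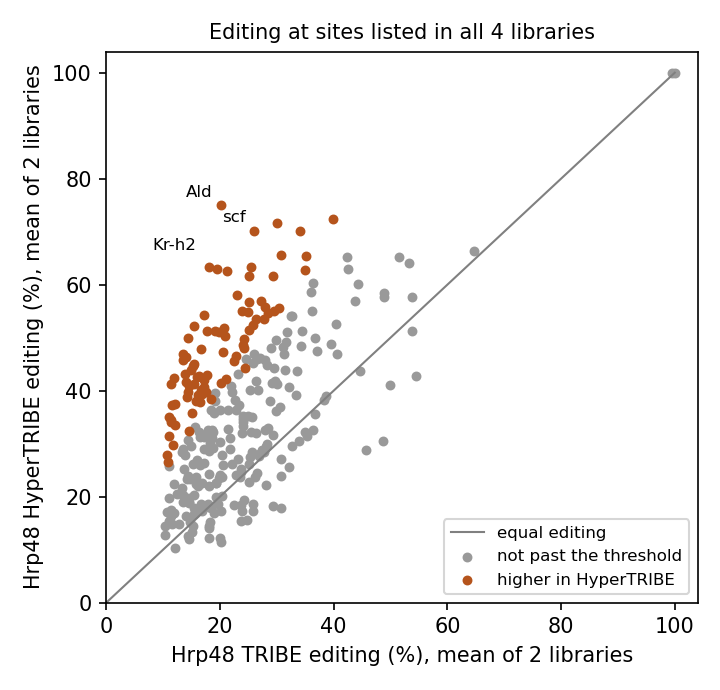
Editing at the 298 sites listed in all 4 Hrp48 libraries, as the mean percentage of the 2 TRIBE libraries (horizontal) and of the 2 HyperTRIBE libraries (vertical), with the line of equal editing. Orange points are the 83 sites higher in HyperTRIBE by limma, and the 2 sites near 100% in both constructs lie at the upper right.

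Gene groups fixed in advance differed in how many tested sites they held. All 4 tested sites of cytosolic ribosomal protein genes rose, among them those of RpL4, RpS24 (15.5% ± 3.33 to 41.3% ± 0.93, SD, n = 2) and RpS29 (10.8% ± 0.26 to 27.9% ± 4.70). Of 4 sites in translation factor genes 3 rose, in Ef1alpha48D, eIF3-S10 and eIF3-S8, and the remaining site, in eIF-5A, was at 17.8% and 32.6%; adjusted over the list alone, 4 passed. Among 9 sites in genes of RNA-binding and splicing proteins 3 rose, in CG10077, SF2 and Hrb87F (3 adjusted over the list alone). The estimate was lower with HyperTRIBE at 3 others, named after their values were seen: another SF2 site (3R, 12166050; 54.6% with TRIBE and 42.7% with HyperTRIBE, limma adjusted p = 0.393), AGO2 (34.9% and 32.2%) and SC35 (53.7% and 51.3%). In the heat shock and chaperone group 2 of 3 sites rose, in Hsc70-5 and Gp93 (3 adjusted over the list alone), and in the endoplasmic reticulum and secretion group 2 of 3, in Sec63 and Chc, the clathrin heavy chain gene (2 adjusted over the list alone). Of the 5 cell cycle sites 1 rose, in geminin (16.9% ± 3.33 to 39.4% ± 3.71), and polo was at 36.2% and 55.1% (1 adjusted over the list alone). None of the 2 mitochondrial, 3 cytoskeletal and adhesion, 2 hemocyte and matrix, and 1 proteasome sites passed with limma, over all sites or adjusted over the list alone. The construct, neuronal and metal response groups had no tested site. The counts for ribosomal proteins over all sites and adjusted over the list alone were both 4.

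The sites of the wild-type fusion lay largely within those of HyperTRIBE. Of the 329 sites listed in both Hrp48 TRIBE libraries, 298 (90.6%, Wilson 95% interval 86.9 to 93.3%) were among the 10851 sites listed in both HyperTRIBE libraries. Of the TRIBE genes, 251 (98.4%, 96.0 to 99.4%) were among the 3220 HyperTRIBE genes. Ald and Lam (2 and 3 sites in both TRIBE libraries, 12 and 16 in both HyperTRIBE libraries) and Sam-S (5 and 25) were in both sets. SCAP, pico, hipk and PlexA had 28 or 29 reproducible HyperTRIBE sites and no reproducible TRIBE site. In the other direction, 2.75% (2.46 to 3.07%) of HyperTRIBE sites and 7.80% (6.92 to 8.77%) of HyperTRIBE genes were in the TRIBE set. These shares were 5.70% and 24.8% when a listing in 1 library of each construct sufficed; the site share was 5.18% within 100 bases and the gene share 2.61% with 2 or more sites per gene.

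HyperTRIBE sites that both TRIBE libraries listed (shared sites) were edited more than the others. The others include sites that a single TRIBE library listed and sites that the other HyperTRIBE library did not list. Reproducible HyperTRIBE sites had medians of 20% and 18.3% in replicates 1 and 2. A listing in both TRIBE libraries at 10% or more also favours strongly edited sites by itself. In HyperTRIBE replicate 1 the 307 shared sites had a median of 33.8% and the 19399 others 15.3%, a difference of 18.5 percentage points (95% interval 16.4 to 20.96). In replicate 2 the medians were 34.4% and 15.4% for 312 and 22491 sites, a difference of 19.02 points (16.3 to 21.5). Shared sites also had more reads, with medians of 60 against 32 in replicate 1 and 76 against 36 in replicate 2. Among sites with at least 50 reads the medians of reads were 67 and 66 in replicate 1, where the editing difference was 19.7 points (16.8 to 21.99), and 76 and 66 in replicate 2, where shared sites still had more reads (by 10, 7 to 14) and the editing difference was 18.99 points (16.3 to 21.6).

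Replicates shared a part of their sites. Of the sites of Hrp48 HyperTRIBE replicate 1, 55.1% (54.4 to 55.8%) were in replicate 2, against 26.3% (23.9 to 28.8%) for Hrp48 TRIBE; of the sites of replicate 2, 47.6% (46.9 to 48.2%) and 23.5% (21.4 to 25.8%) were in replicate 1. Across the 10851 HyperTRIBE sites the editing levels correlated with Pearson's r of 0.73 and Spearman's rho of 0.61, and across the 329 TRIBE sites with 0.67 and 0.53. At the 329 sites, median editing was 25% in TRIBE replicate 1 and 15.8% in replicate 2, and at the HyperTRIBE sites 20% and 18.3%. In Hrb27C, the HyperTRIBE libraries shared 13 sites, in Adar 10 and in Fmr1 8.

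Nearly all sites lay in exons, and the spacing of sites did not simply follow how many a library listed. Sites in introns were 0.579% (0.482 to 0.694%) and 0.697% (0.597 to 0.814%) of the HyperTRIBE sites, 0.240% (0.0815 to 0.702%) and 0.429% (0.197 to 0.932%) of the Hrp48 TRIBE sites, and 0.170% (0.0864 to 0.336%) of the FMRP sites. Between Hrp48 constructs the means differed by 0.304 points (exact permutation test, p = 0.333, n = 2 against 2). A neighbouring site of the same gene within 100 bases was found for 56.0% (55.3 to 56.7%) and 55.2% (54.5 to 55.8%) of HyperTRIBE lines, where a site has a line for each of its genes. The share was 32.5% (30.0 to 35.1%) and 26.5% (24.2 to 28.8%) for TRIBE lines and 23.7% (22.5 to 24.9%) for FMRP lines. For deaminase-alone lines it was 0% (0 to 21.5%) and 29.03% (25.1 to 33.3%). FMRP HyperTRIBE, with 4694 sites, thus had a lower share than deaminase-alone replicate 2, with 459. The difference of 26.1 points between Hrp48 constructs exceeded the spread between replicates (SD 0.592 and 4.24; exact permutation test, p = 0.333), but HyperTRIBE listed 4.88 and 4.79 sites per gene against 1.69 and 1.54. In a test chosen after seeing the data, with HyperTRIBE sites drawn at random down to the numbers of the TRIBE libraries of the same replicate, the shares were 6.78% and 6.22% (medians of 100 draws), below those of TRIBE, and with as many of the most edited HyperTRIBE sites 18.1% and 16.9%. Drawn to the number of FMRP sites they were 21.5% and 18.9%, and 30.7% and 27.7% for the most edited. A random draw separates neighbouring sites by itself, so these values do not show whether the number of sites accounts for the difference. The median distance between neighbouring sites was 123 and 126 bases for Hrp48 HyperTRIBE, 132 and 157 for Hrp48 TRIBE, 148.5 for deaminase-alone replicate 2, and 385 for FMRP HyperTRIBE, whose library listed 2.34 sites per gene.

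The deaminase alone served as the background without an RNA-binding protein. It listed 13 sites in replicate 1 and 459 in replicate 2, and 8 sites in both. CR41602 (XHet, 191112) and CR40677 (XHet, 184929) were listed in all 7 libraries at 95.2% or more. Their current symbols, 18SrRNA-Psi:CR41602 and 2SrRNA-Psi:CR40677, are those of ribosomal RNA pseudogenes. The level hardly differed between constructs, and whether it is editing by the deaminase was not tested. Atpalpha, encoding the sodium pump alpha subunit (3R, 16790761), was edited at 18.2% and 35.3% with the deaminase alone, 54.5% and 33.9% with Hrp48 TRIBE and 50.8% and 69.6% with Hrp48 HyperTRIBE. CG11811 (3L, 10685078) was at 13.04% and 56.5% with the deaminase alone, each on 23 reads, and at 50% and 69.2% with Hrp48 HyperTRIBE. Ubi-p63E, a polyubiquitin gene (3L, 3901658), was at 25% and 27.1% with the deaminase alone, and at 18.7% and 15.8% with Hrp48 HyperTRIBE. The Ef1alpha48D site was at 20.4% and 25.6% with the deaminase alone, 22.8% and 16.2% with Hrp48 TRIBE, and 55.9% with FMRP HyperTRIBE.

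A deaminase-alone library also listed 1.34% (1.14 to 1.57%) of the 10851 Hrp48 HyperTRIBE sites, 6.69% (4.46 to 9.92%) of the 329 Hrp48 TRIBE sites and 2.58% (2.16 to 3.07%) of the 4694 FMRP sites. Nearly all of this came from replicate 2: replicate 1 by itself listed 0.0922%, 2.13% and 0.213%. By gene the shares were 7.89%, 18.04% and 11.4%. Hrp48 HyperTRIBE listed 90.1 times as many sites as the deaminase alone and Hrp48 TRIBE 5.62 times as many (exact permutation test, p = 0.333 for each). These folds were 46.3 and 2.89 without deaminase-alone replicate 1 and 1635 and 102 without replicate 2. Each deaminase-alone library comes from a library set of its own, as the file headers name them, so construct and set cannot be told apart.

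FMRP HyperTRIBE listed 4694 sites in 2003 genes in its single library. The 10 genes with most FMRP sites were none of the 10 with most reproducible Hrp48 HyperTRIBE sites, which had to be in both libraries. Unrelated lists this short, from 2003 and 3220 genes, would mostly not overlap either. CG5604, faf, Not1 and Lk6 held at least as many sites in each Hrp48 HyperTRIBE library as with FMRP. The FMRP list was led by poe (27 sites, against 8 and 8 with Hrp48 HyperTRIBE), Rme-8, an endocytic DnaJ protein gene (22 against 17 and 25), CG5604 (22 against 24 and 24) and CG7518 (20 against 6 and 7). Dhc64C, the cytoplasmic dynein heavy chain gene, held 18 FMRP sites against 4 and 6, and hyd, a ubiquitin ligase gene, 18 against 4 and 3. For faf, a deubiquitinase gene, the numbers were 18 against 35 and 25, for Not1, the scaffold of the CCR4-NOT complex, 17 against 21 and 17, for CG16974 16 against 10 and 8, and for the kinase gene Lk6 15 against 20 and 18. Hel89B (6 FMRP sites), CG14803 (4), CG16989 (3), Grip84 (3) and CG32164 (2) had FMRP sites and none in either Hrp48 HyperTRIBE library. In contrast, pcs (25 reproducible Hrp48 sites), PGAP3 (19), ImpL2, encoding an insulin-binding protein (18), Axn, encoding Axin (15), and cnc, the fly Nrf2 homologue (15), had no FMRP site. Axn and cnc had a median of 26.5 and 31 reads at their Hrp48 HyperTRIBE sites.

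Of the FMRP sites, 47.1% (45.6 to 48.5%) were reproducible Hrp48 HyperTRIBE sites, 69.9% (68.5 to 71.2%) were in at least 1 Hrp48 HyperTRIBE library, and 1415 were in neither. Of the 2003 FMRP genes 1607 (80.2%, 78.4 to 81.9%) had a reproducible Hrp48 HyperTRIBE site. Sites shared with FMRP were the more strongly edited Hrp48 sites: FMRP listed 9.81% (8.63 to 11.1%) of the quintile of reproducible Hrp48 HyperTRIBE sites with the lowest editing and 36.7% (34.7 to 38.7%) of the quintile with the highest. At the 2209 shared sites the editing levels of the constructs correlated with Spearman's rho of 0.34 (0.30 to 0.37) and Pearson's r of 0.39, while the Hrp48 HyperTRIBE replicates correlated at these sites with a rho of 0.71 and an r of 0.78. Median editing there was 24.4% with Hrp48 and 17.5% with FMRP. With 1 library for FMRP, and a library set of its own, these values compare libraries, not conditions.

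**Figure D3:**
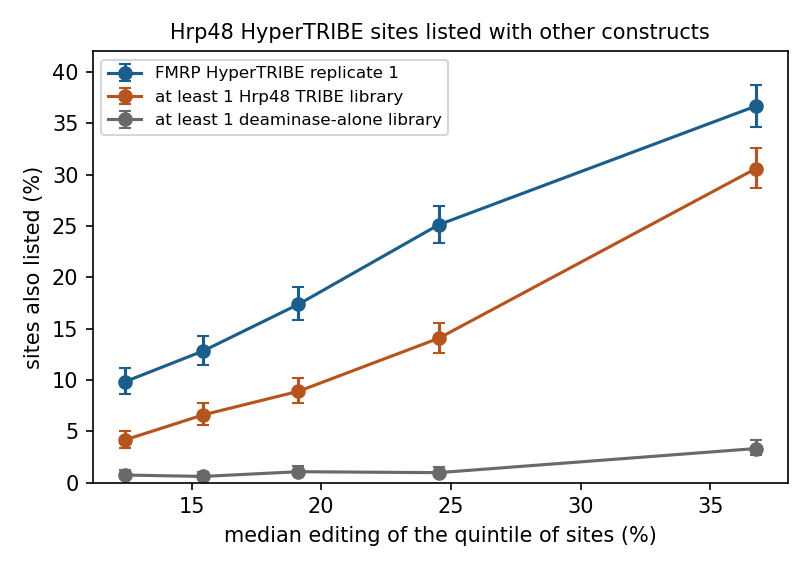
Share of the 10851 reproducible Hrp48 HyperTRIBE sites that other libraries also list (vertical, percent, bars are Wilson 95% intervals), by quintile of editing in Hrp48 HyperTRIBE (horizontal, median percent of the quintile). The FMRP share goes from 9.81% to 36.7%, and the share in at least 1 Hrp48 TRIBE library from 4.15% to 30.6%.

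The fixed gene groups were compared between constructs by Fisher's exact test over genes, which are not replicates. Among genes with reproducible Hrp48 HyperTRIBE sites, 7.80% had a reproducible TRIBE site. By Fisher's exact test the share was 7 of 34 (20.6%) for RNA-binding and splicing proteins (p = 0.0139, adjusted p = 0.181), 3 of 14 for the cell cycle group (adjusted p = 0.469), 4 of 27 for translation factors, 3 of 19 for chaperones and 4 of 27 for secretion. It was 4 of 48 for ribosomal proteins, 2 of 18 for mitochondrial respiration, 2 of 41 for the cytoskeletal group, 2 of 18 for hemocyte and matrix genes, and 1 of 17 for the proteasome. It was 0 of 3 for construct genes, 0 of 3 for neuronal markers and 0 of 4 for metal response genes. None of the 13 lists passed the adjusted threshold, and 1 had an unadjusted p under 0.05. With genes of at least 50 median reads the overall share was 19.3%, and 5 lists above the overall share among all genes lay below it: ribosomal proteins (4 of 43), mitochondrial respiration (1 of 12), hemocyte and matrix genes (1 of 11), chaperones (3 of 18) and secretion (4 of 23). None of the lists passed there either.

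FMRP sites were present in 55.4% of the genes with an FMRP or a reproducible Hrp48 HyperTRIBE site. This background includes 396 genes that enter only through an FMRP site and so raise the shares by construction. Proteasome genes had the lowest share, 4 of 18 (22.2%, Fisher's exact test p = 0.00708, adjusted p = 0.0920): REG, Rpn8, Rpn10 and Rpn11 had 2 or 3 reproducible Hrp48 sites each and no FMRP site. Cytosolic ribosomal protein genes had 36 of 52 (69.2%, adjusted p = 0.318), with RpS29 and RpL27 at 3 FMRP sites each. The others were 18 of 28 for translation factors, 22 of 36 for RNA-binding and splicing proteins (pum held 13 reproducible Hrp48 sites and no FMRP site), 9 of 18 for mitochondrial respiration, 26 of 42 for the cytoskeletal group and 13 of 18 for hemocyte and matrix genes. They were 8 of 19 for chaperones, 16 of 23 for the cell cycle, 14 of 28 for secretion, 3 of 3 for construct genes, 2 of 3 for neuronal markers and 3 of 5 for metal response. None of these lists passed the adjusted threshold in this Fisher test, and 2 had an unadjusted p under 0.05. With genes of at least 50 median reads 2 did, ribosomal proteins (33 of 46, 71.7%, against 50.1%; adjusted p = 0.0394) and translation factors (17 of 21, 80.95%; adjusted p = 0.0394). The 50-read minimum does not make the coverage of a list equal to that of the other genes. Median reads with Hrp48 HyperTRIBE were 121 for ribosomal proteins, 68.5 for translation factors and 97 for chaperones, which did not pass. What coverage adds to these shares was not tested. In a test chosen after seeing the data, among the genes with a reproducible Hrp48 HyperTRIBE site alone (49.9% with an FMRP site), no list passed. With at least 50 median reads there (48.6%), ribosomal proteins (30 of 43, 69.8%) and translation factors (16 of 20) passed by Fisher's exact test (adjusted p = 0.0331 for each), and the cell cycle group had 7 of 14 in place of 16 of 23 at any coverage. With the wider background and 50 reads, 3 lists changed sides of the overall share: mitochondrial respiration (7 of 12), the cell cycle (2 of 4) and metal response (0 of 1).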

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

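Across 113 alternatives to 46 results, 64 gave the same result, 32 moved it, 4 made it stronger and 13 turned its direction. Same means within 1 SD of replicates for folds and differences of means, within the 95% interval for shares, medians and correlations, within 1.5 times for counts of sites, and an equal count or the same side for gene lists; the deaminase-alone replicates (13 and 459 sites) differ so much that their folds count as the same over a wide range. Leaving out sites seen with the deaminase alone, sites near full editing, or either deaminase-alone replicate as background, spacing at equal numbers of sites, and FMRP lists among Hrp48 genes alone, were chosen after seeing the data. A random draw of sites separates neighbours by itself. Direction turned for spacing, where HyperTRIBE minus TRIBE was -22.96 points with sites drawn at random to equal numbers and -11.98 with the most edited. It turned for 8 gene lists with deep genes (share minus the overall share, in points): against TRIBE -10.01 for ribosomal proteins, -10.98 for mitochondrial respiration, -10.2 for hemocyte and matrix genes, -2.64 for chaperones and -1.92 for secretion, and against FMRP 8.28 for mitochondrial respiration, -0.0559 for the cell cycle and -50.06 for metal response. Among Hrp48 genes alone it turned for mitochondrial respiration (0.0932, and 9.71 with deep genes) and metal response (-48.6 with deep genes). Neuronal markers had no deep gene and so no value. The fold of Hrp48 HyperTRIBE over Hrp48 TRIBE sites was 27.8 at 50 reads or more, a minimum that favours the deeper HyperTRIBE libraries. It was 20.05 at 20% editing or more and 14.9 to 17.2 with a library left out. After thinning it was 8.53. Thinning can only remove sites, while its ratios may overstate the depth of the TRIBE libraries. Over the deaminase alone, the folds were 46.3 to 1635 for HyperTRIBE and 2.89 to 102 for TRIBE with a library left out, and 166.9 and 6 at 50 reads and 131.8 and 6.58 at 20% editing. The count of sites higher in HyperTRIBE was 31 at 50 reads or more (fewer sites tested), 215 where 1 TRIBE library sufficed (more sites tested), 127 with pooled reads (taken as independent), and 1 to 171 with a library left out, where the lone library is assumed to vary like the others. Without TRIBE replicate 2, 81 sites were higher and 9 lower. With the replicate block, 83 sites were higher, as without it; the replicate differences of the constructs correlated at -0.013 across sites, so the shared numbers were not taken as pairs. The share of TRIBE sites found by HyperTRIBE was 94.5% within 100 bases, 77.7% for 1 library and 94.9% at 50 reads; the reverse share was 5.18%, 5.70% and 1.99%. For genes the reverse share was 24.8% for 1 library and 2.61% with 2 sites or more. The intron difference was 0.479 points at reproducible sites, where 0 of 329 TRIBE sites (0 to 1.15%) are too few to compare. Shared genes in place of sites gave 7.89%, 18.04% and 11.4% for the deaminase alone as background of Hrp48 HyperTRIBE, Hrp48 TRIBE and FMRP, and replicate 1 as the only background 0.0922%, 2.13% and 0.213%. The FMRP overlap was 69.9% for 1 Hrp48 library and 59.0% at 50 reads, and replicate agreement at 50 reads was 62.8% of HyperTRIBE replicate 1 and 33.9% of TRIBE replicate 1, but 44.3% and 27.3% of replicate 2 (47.6% and 23.5% over all sites). With deep genes 2 gene lists passed in place of 0, and 2 among deep Hrp48 genes, with coverage not matched to the other genes. Causes not named here were not tested. Sites under 20 reads or 10% editing are not listed, so editing there is unseen. Neighbouring bases were not run.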

Other observations

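Tests of the mixed-in RNA, the deaminase level and the Arc1 cluster were chosen after the result was seen.

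Sites of Hrp48 HyperTRIBE that other constructs also listed were the more strongly edited ones. Of the quintile of reproducible sites with the lowest editing (median 12.4%), 4.15% (95% interval 3.38 to 5.07%) were in at least 1 Hrp48 TRIBE library, and of the quintile with the highest (median 36.8%) 30.6% (28.7 to 32.6%). Median coverage of these quintiles was 43 and 39.8 reads. The shares also rose with coverage: between the lowest quintile of reads (median 26.5) and the highest (80), from 4.51% to 22.03% for at least 1 Hrp48 TRIBE library and from 11.2% to 24.98% for FMRP. FMRP sites listed in neither Hrp48 HyperTRIBE library had a median of 13.04% editing and 28 reads, against 16.3% and 34 reads for the others.

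Genes with most deaminase-alone sites in replicate 2, chosen after their values were seen, were Arc1 (12 sites), pncr009:3L (12), CycG (10), Lk6 (9) and kst, encoding the heavy spectrin Karst (9). Hrp48 HyperTRIBE listed 2 and 4 sites in Arc1, 11 and 8 in pncr009:3L and 2 and 5 in kst. For mbc, 7 sites were listed in deaminase-alone replicate 2, 0 and 1 with Hrp48 HyperTRIBE and 2 with FMRP.

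Deaminase-alone replicate 2 listed 459 sites and replicate 1 listed 13. Lower read depth in replicate 1 was tested by thinning replicate 2 by the lowest coverage ratio (0.609) at the 8 sites listed in both, which left a median of 133 sites (117 to 153 over 100 draws), well above 13; those 8 sites had to be covered in both, so the ratio may overstate the depth of replicate 1. At Ef1alpha48D (2R, 7782921) replicate 2 had 22.4% editing on 116 reads and replicate 1 did not list the site, although it had 108 reads 12 bases away. RNA of a fusion library analysed here, mixed into replicate 2 as the source of all its sites, is argued against by the 45.3% (40.8 to 49.9%) of them that any of these 5 libraries listed; each of the 5 shared at least 51.3% of its sites with the others. At sites with at least 50 reads and 20% editing the share was 15 of 24 (42.7 to 78.8%), against at least 95.6%. Such RNA as the source of a part of the sites was not tested. RNA of a fusion library not analysed here stays open, since 251 sites were in none of the 5. A lower level of the deaminase in replicate 1 stays open, since 0 Adar sites were listed in these libraries, and the design names no biological difference between the replicates, so none was tested.

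In Arc1, whose protein forms capsids that carry RNA, 11 of the 12 sites of deaminase-alone replicate 2 lay within 369 bases of an exon (2R, 10246089 to 10246457), with 10.8% to 74.2% editing on 21 to 80 reads. Of the 12 sites, 2 were listed in another library, 1 of them in the cluster. A sequence variant of the cells against the reference, which would recur in libraries of the same cell line, and too few reads over the cluster in the other libraries both stay open. The second set of base counts held at least 10 reads and 0 of the edited base at every listed site. What was sequenced for it is not given, so it cannot settle whether a variant is present. Reads of another library within the cluster are given at 1 site (10246089, 92 reads in Hrp48 HyperTRIBE replicate 2), and 1 unlisted cluster site lies within 100 bases of a site with at least 50 reads in another library. No biological explanation was tested.

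Editing in Hrp48 TRIBE replicate 1 lay above that in replicate 2 at sites listed in both. Lower read depth in replicate 1 with the 10% threshold would remove the difference at deep sites, but at the 59 sites with at least 50 reads in both libraries the median difference was 6.90 percentage points (95% interval 5.09 to 8.73), and replicate 1 was higher at 54. A difference in expression of the construct or between the library sets 02 and 03 stays open. The Hrp48 HyperTRIBE replicates of the same sets differed by a median of 0.910 points over their shared sites.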
